A study of Arabidopsis thaliana with 3 samples.

How the data were processed

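Anti-GFP chromatin immunoprecipitation followed by sequencing was done, per the labels, on 7-day-old seedlings of Col-0, OX TZP and OX ZFHD10, 1 library each. Tissue was fixed with 1% formaldehyde for 15 minutes, libraries were made from 1 ng of DNA with 12 cycles of PCR to a length of about 400 bp, and single-end reads of 75 bp were sequenced, per the labels' protocols. The submitters' processing notes name cutadapt 1.5, Bowtie 0.12.7, SICER 1.1, HOMER and the build TAIR10, with no roles. The names of the deposited lists carry a window of 50 bp, a gap of 200 bp and a false discovery rate of 0.1. The deposited values are whole-number counts of reads per island, not scaled for depth or length; that the fourth column is a read count rests on its values and on the format of SICER's island lists, since no label states it. Which library served as the control is not given in the sources used here, nor is the treatment of duplicate reads. A loose false discovery rate admits weak islands, and a gap of 200 bp joins neighbouring windows, so that island number and length depend on depth. Islands start and end on 50 bp windows, which limits their positions to that step.

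Groups were taken from the genotype label. Positions were written counted from 1. Reads were divided by island length in kb. Islands on organelle genomes were left out of the comparisons with genes. Gene names, types and neighbours came from a gene table of the assembly TAIR10.1, which holds 27432 protein-coding genes on the 5 nuclear chromosomes. To check that both builds share their positions, the offset at which OX ZFHD10 midpoints fell inside genes least often was found in 25 segments of the chromosomes, searching 3000 bp to either side. It lay within 200 bp of 0 in 24 of them and at most 300 bp from it in any. The gene table has no strand, exons or sequence. Promoters fixed in the plan were therefore replaced by gene ends, from 1000 bp outside to 100 bp inside either end, the distance to the upstream gene by the summed distance to both neighbours, and the nearest transcription start by the nearest gene. Exons, introns and untranslated regions were not separated, and sequence motifs were not analysed here. Pseudogenes were those so typed in the gene table. Transposable elements were not examined as a separate type, so the pseudogene shares and the pseudogene-rich bins may include them. Gene ends of neighbours overlap, so 1 island can count for several genes.

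The overlap of the lists, by at least 1 bp, was compared with 1000 random placements that kept chromosome and length, and midpoints were treated in the same way. An observed value outside the central 95% of placements was taken as different from placement. Gene lists were compared with 10000 random lists of the same size drawn from protein-coding genes matched on 10 classes of the distance to neighbouring genes, with the same rule. Both rules used the percentile of the observed value, with ties counted at 0.5. A share in a short list could thus pass the rule while equal to the limit of the central 95%. Such cases are stated for the main comparisons and for some of the alternatives. These comparisons describe the lists, and no p-value was made from islands or genes. The 10 gene lists held 266 genes, of which 265 were located. The lists, the named-gene rule and the main tests were fixed before the data were examined, while the words that define the 21 families and the bins of 100 kb with more pseudogenes than protein-coding genes were chosen afterwards. The rule named, per line, the 10 genes with the densest islands at a gene end, the 10 with the best sum of ranks over both lines, up to 4 members of each list, all members of the light signalling, auxin and brassinosteroid lists with islands of each line, and both introduced genes. Other members named in the text were chosen after their values were seen. Where a gene had several islands, the densest is given.

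Intervals are 95% Wilson intervals for shares and 95% exact Poisson intervals for reads per kb. They cover counting error only and treat reads and islands as independent. Reads amplified by PCR are not independent molecules, and neighbouring islands may not be independent, so the intervals may be too narrow. The fewest reads in an island were 47 in OX TZP and 55 in OX ZFHD10. Alternatives changed the overlap, the gene-end window (500 or 2000 bp outside), the placement, the islands kept, the assignment of genes and the matching of random lists. The overlap method was tested on simulated lists. With no overlap planted, 1 of 40 runs left the central 95%, and with 5% planted all 40 did and 5.03% was recovered. Both simulated lists were placed at random along each chromosome, so these runs do not cover lists that share only a regional density of islands. The list method was tested on simulated lists of 40 among 27432 genes, of which 50 of 1000 left the central 95% with nothing planted, and 666 of 1000 with 30% of members planted. In these runs each gene had an island independently of its neighbours, at a rate near that of OX TZP. They therefore do not cover the higher share of genes with an island in OX ZFHD10, nor shorter lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.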

Results

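Chromatin bound by green fluorescent protein (GFP) fusions was immunoprecipitated from 7-day-old Arabidopsis thaliana seedlings kept in low blue light and sequenced. The series had 3 libraries, 1 each of the wild type Col-0, a line overexpressing TZP (OX TZP) and a line overexpressing ZFHD10 (OX ZFHD10). TZP is a zinc-finger protein of light signalling, and ZFHD10 belongs to the plant zinc-finger homeodomain (ZF-HD) family and was taken here as HB23 (AT5G39760), since the labels give no locus. Lists of enriched regions, called islands, were analysed for OX TZP and OX ZFHD10, and no list of Col-0 was used here. The OX TZP list held 11684 islands with 2112203 reads, and the OX ZFHD10 list held 16122 islands with 4731495 reads. On the 5 nuclear chromosomes the islands covered 12.1 Mb (10.1%) in OX TZP and 16.6 Mb (13.9%) in OX ZFHD10, with median lengths of 900 and 800 bp. Within the OX TZP list the 5th and 95th percentiles of read density were 141 and 207 reads per kb of island, a ratio of 1.47, and within the OX ZFHD10 list 192 and 411, a ratio of 2.14. Each group had 1 library, so no difference between the lines has a replicate check and none was tested. Intervals given below cover counting error, and since whole-library depth is unknown, densities are compared within a list and not between lists.

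The genes of both introduced proteins carried some of the densest islands of their own line, with ZFHD10 taken as HB23. Extra copies of an introduced sequence in an overexpression line would add reads over it without binding. These islands alone therefore do not tell binding at either gene from extra copies. Over TZP (AT5G43630) the OX TZP list had an island at chromosome 5 positions 17527151 to 17530300 (TAIR10) with 1872 reads, or 594 reads per kb (95% Poisson interval 568 to 622). It ranked 3 of 11675 nuclear islands, lay wholly inside the gene and covered 79.8% of it. Over ZFHD10 (AT5G39760) the OX ZFHD10 list had an island at chromosome 5 positions 15910901 to 15913300 with 1316 reads, or 548 reads per kb (519 to 579), which ranked 80 of 16122 and covered the whole gene. Unlike the island over TZP, it reached beyond both ends of the gene, and 63.0% of it lay inside. Another lay outside the gene at 15913601 to 15914400 with 426 reads per kb (382 to 474). At TZP the OX ZFHD10 list also had an island inside the gene, at 17527201 to 17530250, with 227 reads per kb (210 to 244), which was 0.865 times the median of its list. Another at 17526001 to 17526850 lay inside the gene to 22.5%, with 222 reads per kb (192 to 256). At ZFHD10 the OX TZP list had an island beside the gene, at 15910751 to 15911300, with 191 reads per kb (156 to 231).

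**Figure D1:**
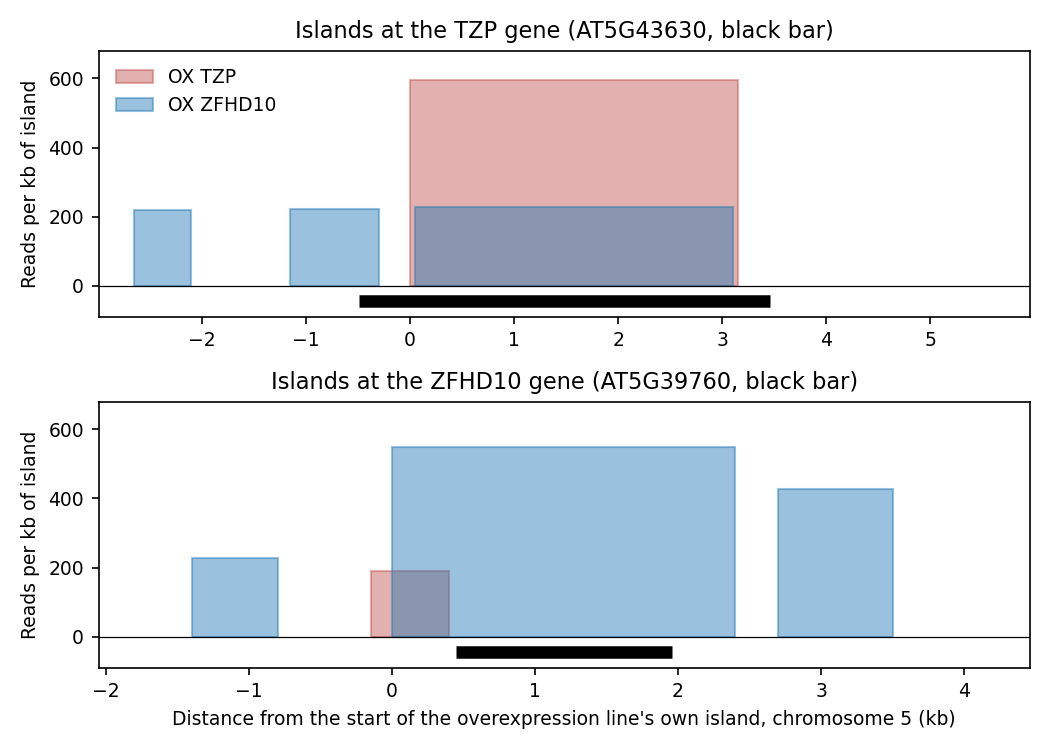
Islands at the TZP and ZFHD10 genes, drawn to scale; the horizontal axis is the distance in kb from the start of the island of the line overexpressing that gene, the height of a box is the reads per kb of island, and the black bar is the annotated gene. The OX TZP island over TZP reaches 594 reads per kb and the OX ZFHD10 island over ZFHD10 reaches 548.

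Whether TZP and ZFHD10 occupy the same places was asked by overlapping the lists. Of the 11675 nuclear OX TZP islands, 5566 overlapped an OX ZFHD10 island, or 47.7% (95% Wilson interval 46.8 to 48.6), against a mean of 23.6% over 1000 random placements of the OX ZFHD10 islands on the same chromosomes. In the other direction 5355 of 16122 OX ZFHD10 islands, or 33.2% (32.5 to 33.9), overlapped an OX TZP island, against 17.7% by placement. Shifting the OX TZP islands by 5 or 10 kb to either side lowered the overlap to a mean of 30.9%. Shifts of 500 bp left 45.6% and 45.1%, and shifts of 1000 bp left 37.8% and 37.6%. The overlap therefore does not place both lists at the same position within the length of an island. The overlapping OX TZP islands lay at gene ends more often than the others, 63.1% against 32.4%, while for OX ZFHD10 these shares were 75.8% and 73.4%. Of all OX ZFHD10 islands, 74.2% were centred at gene ends, against 40.2% by placement. OX TZP islands picked for overlapping them would lie there more often in any case, so the 63.1% is not separate evidence of shared places. Across 5786 overlapping pairs of islands the read densities of the lists had a Spearman correlation of 0.136 and a Pearson correlation of 0.110; pairs of islands are not independent replicates. Part of the excess overlap may come from a control library shared by both island calls, which is not given in the sources used here.

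**Figure D2:**
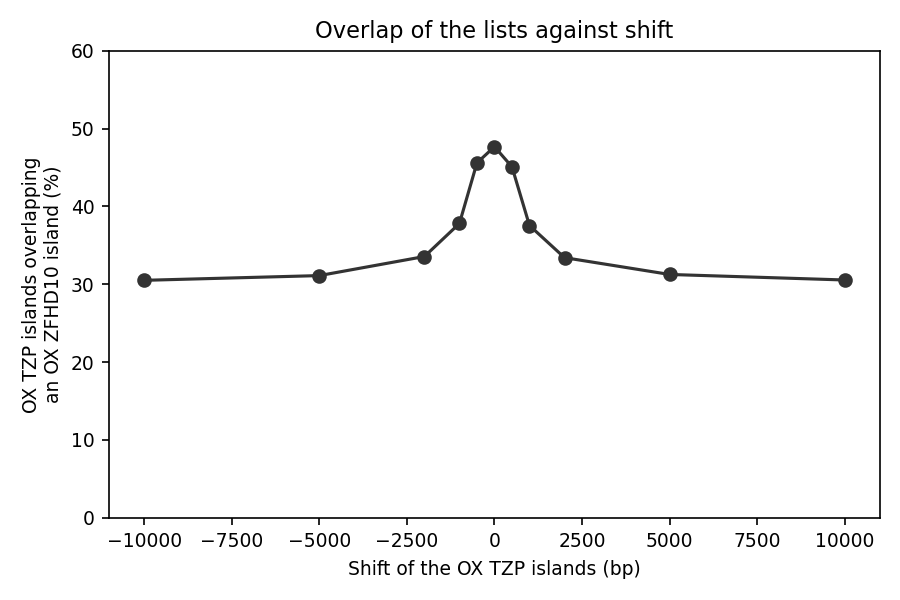
Share of OX TZP islands that overlap an OX ZFHD10 island (vertical axis, %) after all OX TZP islands were shifted along the chromosome (horizontal axis, bp); each point is 1 shift of the whole list. The share is 47.7% with no shift and averages 30.9% at shifts of 5000 and 10000 bp.

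At the level of genes, 8666 protein-coding genes had an island of each line at a gene end. They included PIF3, PIF4, PIF5 and PIF7, basic helix-loop-helix (bHLH) factors that promote hypocotyl growth, the blue-light receptor gene CRY2 and the red and far-red light receptor genes PHYA and PHYB, and HY5, a regulator of seedling development in light. A gene end was the stretch from 1000 bp outside to 100 bp inside either end of the gene. The OX TZP list reached 11122 of 27432 protein-coding genes (40.5%) and the OX ZFHD10 list 17853 (65.1%), and lists of these sizes drawn independently would share 7238 genes. Of the OX TZP genes, 77.9% were also OX ZFHD10 genes, 2456 were found in OX TZP alone, 9187 in OX ZFHD10 alone and 7123 in neither list. In 6838 of the 8666 shared genes (78.9%) an island of each line at the same gene also overlapped the other.

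The 10 genes with the densest islands at a gene end differed between the lists. Among those of OX TZP, AT2G02620 also had an overlapping OX ZFHD10 island. Among those of OX ZFHD10, ZCF61, MPK2, AT1G80850 and PLMT also had overlapping OX TZP islands. In OX TZP the island ranked 2, at chromosome 5 positions 3253051 to 3253350 with 603 reads per kb (519 to 698), lay at AT5G10336 and AT5G10340, and another at chromosome 1 positions 10598301 to 10599600 with 408 reads per kb (374 to 445) lay at AT1G30140 and JAZ8, which encodes a repressor of jasmonate responses. The other 6 of the 10 genes with the densest OX TZP islands were AT1G40104, AT2G02620, AT2G02630, AT2G02635, AT2G07981 and AT2G08986, and AT1G40104, AT2G07981 and AT2G08986 lay in 100 kb bins with more annotated pseudogenes than protein-coding genes. In OX ZFHD10 the densest island, at chromosome 4 positions 7279201 to 7279700 with 790 reads per kb (714 to 872), lay at AT4G12190. It was followed by islands at AT5G40180, AT5G40190 and the protease gene DEG9 (767 reads per kb), at AT1G80850 and PLMT (749 reads per kb), at ZCF61 and the kinase gene MPK2 (748 reads per kb) and at AT1G20300 and AT1G20310 (731 reads per kb). The 10 genes that ranked best over both lists were AT2G22660, AT1G67910, AT3G15480, AT3G15490, AT3G27520, GC6, SBP1, SAP10, AT4G25390 and AT5G61997. At AT2G22660 the OX TZP island (9631551 to 9631950 on chromosome 2) had 248 reads per kb and the OX ZFHD10 island (9631501 to 9632100) had 730.

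Genes of light signalling had islands more often than random genes in both lines. In OX TZP 23 of 41 members had an island at a gene end (56.1%, against a mean of 39.7% and a central 95% of 24.4 to 53.7% in 10000 random lists matched on the distance to neighbouring genes), and in OX ZFHD10 34 of 41 (82.9%, against 63.7%, 48.8 to 78.0%). The 22 members with an island of each line were CRY2, PHYA, PHYB, UVR8, HY5, HYH, PIF3, PIF4, PIF5, PIF7, BBX20, BBX21, BBX22, BBX24, BBX25, SPA3, SPA4, FHY1, FHY3, FAR1, CIB1 and PCH1, and at 16 of them the islands overlapped. At PIF3 the OX TZP island at chromosome 1 positions 3075351 to 3075850 had 196 reads per kb (159 to 239) and the OX ZFHD10 island at 3075101 to 3077200 had 396 (369 to 424). At PIF4, on chromosome 2, the OX TZP island at 17885551 to 17886850 had 171 reads per kb (149 to 195) and the OX ZFHD10 island at 17885501 to 17887050 had 236 (213 to 262). At HY5 the values were 177 (150 to 206) and 331 (288 to 378). COP1, CRY1, HFR1, PIL1 and 8 other members had an OX ZFHD10 island and no OX TZP island, RUP2 had an OX TZP island alone, and PIF1, BIC2, PHOT1, DET1, PHYE and PHYC had none. The 20 housekeeping genes, taken as a comparison list, lay above their random lists in OX ZFHD10 as well, with 20 (100%, against 65.6%). In OX TZP they lay on the upper limit of the central 95%, with 13 (65.0%, against 41.1%, 20 to 65.0%; percentile 98.3). Over gene bodies with random lists matched on gene length, the OX TZP shares of the light signalling and housekeeping lists were inside the central 95%. The housekeeping share in OX TZP was also inside it for the nearest gene and among the islands with the most reads.

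Auxin genes lay above their random lists in OX ZFHD10, where 34 of 48 had an island (70.8%, against 53.9%, 39.6 to 66.7%). In OX TZP 23 of 48 did (47.9%, against 35.7%, 22.9 to 50%), inside the central 95%. Islands of each line were found at 16 members: the receptor genes TIR1, AFB1, AFB2 and AFB3, the response factor genes ARF6, ARF8 and ARF19, GH3.3, GH3.5 and GH3.6, which encode enzymes that conjugate auxin, IAA4, IAA14, SAUR15, HAT2, YUC9 and LAX3. At GH3.6 the OX TZP island at chromosome 5 positions 22134351 to 22134900 had 340 reads per kb (293 to 392), rank 40 of its list, and the OX ZFHD10 island at 22133601 to 22135200 had 356 (327 to 386). At GH3.5, on chromosome 4, the values were 186 (168 to 205) and 476 (452 to 501). Members with an OX TZP island alone included SAUR19, SAUR20, SAUR21, TAR2, YUC3 and IAA5, and IAA19, IAA29, YUC8, PIN3, PIN7, PKS1 and 12 other members had an OX ZFHD10 island alone. The OX ZFHD10 share was inside the central 95% without matching and over gene bodies, and the OX TZP share lay on its upper limit when genes were assigned by nearest midpoint or without the pseudogene-rich bins. With all islands at gene ends the housekeeping genes had higher shares in both lines.

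The genes of brassinosteroid, gibberellin and growth bHLH factors had an island in 25 of 31 cases in OX ZFHD10 (80.6%, against 56.3%, 38.7 to 74.2%) and in 14 of 31 in OX TZP (45.2%, against 36.7%, 19.4 to 54.8%), so that the list left the central 95% in OX ZFHD10. Members with an island of each line were BRI1 and BAK1, the brassinosteroid receptor and its partner, BIN2, BZR1, BES1, BAS1, DET2, BEE2, BEE3, RGL1, RGL3 and GID1C. At BRI1 the OX TZP island at chromosome 4 positions 18324451 to 18324750 had 220 reads per kb (170 to 280) and lay within an OX ZFHD10 island at 18317551 to 18325200 with 412 (398 to 427). Of the genes of cell wall expansion, 16 of 20 had an OX ZFHD10 island (80%, against 57.8%, 35 to 80%, on the upper limit; percentile 98.1) and 11 an OX TZP island (55.0%, against 37.5%, inside the central 95%). CESA1, CESA3 and CESA6, which encode cellulose synthases, and XTH5, XTH18, XTH19, XTH22, XTH24, XTH33 and EXPA4 had islands of each line. At CESA3 the OX TZP island had 174 reads per kb (150 to 200) and the OX ZFHD10 island 461 (425 to 499). In OX ZFHD10 these shares were inside the central 95% without matching and over gene bodies, and cell wall expansion also among the islands with the most reads and without the pseudogene-rich bins. With all islands at gene ends the housekeeping genes had higher shares than either.

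Clock genes had an island in 14 of 22 cases in OX TZP (63.6%, against 42.3%; percentile 97.52 of the random lists, on the upper limit) and in 19 of 22 in OX ZFHD10 (86.4%, against 69.2%, inside the central 95%). GI, CCA1, TOC1, PRR9, ELF3, ELF4, LUX, LNK1, RVE1, RVE4 and CHE had islands of each line, and at all 11 the islands overlapped. At GI the OX TZP island at chromosome 1 positions 8060701 to 8061300 had 247 reads per kb (209 to 290) and the OX ZFHD10 island at 8060601 to 8061950 had 270 (243 to 299). Flowering-time genes left the central 95% in OX ZFHD10 with 14 of 17 (82.4%, against 56.9%) and not in OX TZP with 9 of 17 (52.9%, against 36.6%); TEM1, CDF2, CDF3, CDF5, TOE1, SPL3, SVP and LFY had islands of each line, and FT had an OX TZP island alone. The ZF-HD family and its short relatives, the MIF genes, lay inside the central 95% in both lines, with 9 of 17 (52.9%) in OX TZP and 13 of 17 (76.5%) in OX ZFHD10. At HB24 the values were 196 reads per kb (166 to 230) and 458 (431 to 487). The clock share in OX TZP was inside the central 95% among the islands with the most reads and over gene bodies, and that in OX ZFHD10 left it for the nearest gene and lay on its upper limit among the islands with the most reads and without matching. The flowering share in OX ZFHD10 was inside it among the islands with the most reads, over gene bodies and without matching. With all islands at gene ends the housekeeping genes had higher shares than the clock and flowering lists.

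Photosynthesis and pigment genes lay inside the central 95% in both lines, with 8 of 30 (26.7%, against 39.8%) in OX TZP and 21 of 30 (70.0%, against 63.2%) in OX ZFHD10. HEMA1, an enzyme gene of chlorophyll synthesis, had an OX TZP island of 218 reads per kb (174 to 268) and an OX ZFHD10 island of 476 (428 to 528), and PORC, GUN5, LHCA4, LHCB4.1, FLS1 and CHS also had islands of each line. The stress response list lay above its random lists in both lines, with 14 of 19 (73.7%, against 40%, 21.1 to 63.2%) in OX TZP and 17 of 19 (89.5%, against 64.2%, 42.1 to 84.2%) in OX ZFHD10. ZAT10, JAZ1, WRKY33, WRKY40, ZAT12, CBF1, CBF2, NCED3, ABI1, RD29A, RAB18, HSP101 and HSP18.2 had islands of each line. At ZAT10 the OX TZP island at chromosome 1 positions 9647201 to 9649550 had 217 reads per kb (198 to 236), and the OX ZFHD10 island at 9647251 to 9649500 had 349 (325 to 375). Among the housekeeping genes, ACT2, ACT7, ACT8, UBQ10, EF1A, GAPC1, TUA3, HSC70-1, H2AX, RPL4A, PP2AA3, TIP41L and SAND had islands of each line, and at ACT7 these had 254 reads per kb (204 to 313) and 290 (259 to 325). The stress response shares were inside the central 95% when genes were assigned by nearest midpoint.

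**Figure D3:**
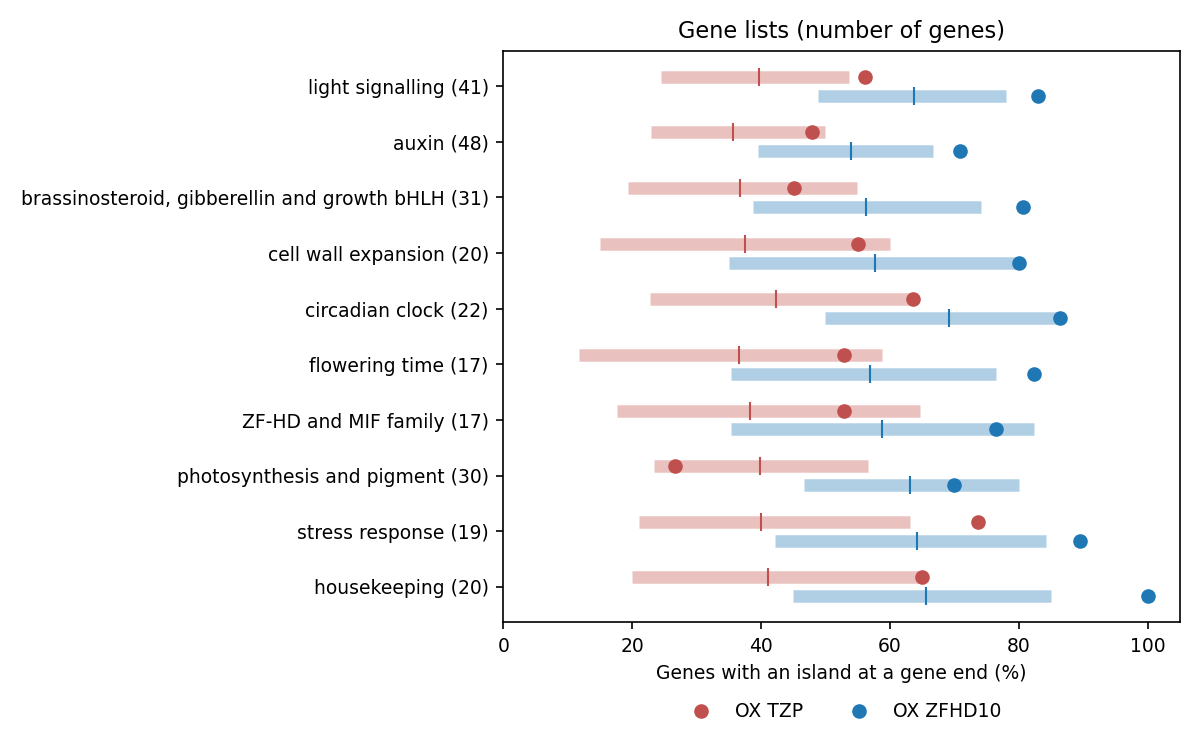
Share of the genes of each list with an island at a gene end (horizontal axis, %) in OX TZP and OX ZFHD10; points are the observed shares, bars the central 95% and ticks the mean of 10000 matched random lists, and the number of genes stands beside each list. The housekeeping list reaches 100% in OX ZFHD10, above the light signalling list at 82.9%.

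Among families found by words in gene names, WRKY, MYB and bZIP transcription factors had more OX TZP islands than matched random genes. GRAS factors lay on the upper limit of the central 95%, with 8 of 11 (72.7%, against 40.3%, 9.09 to 72.7%). In OX ZFHD10, 7 families lay above: WRKY, ethylene-responsive factors, B-box, Aux/IAA, ribosomal proteins, protein kinases and F-box. WRKY factors had an island in 37 of 72 cases in OX TZP (51.4%, against 38.8%) and in 59 of 72 in OX ZFHD10 (81.9%, against 60.8%), and bZIP factors in 26 of 46 in OX TZP (56.5%, against 38.4%). MADS factors, which include regulators of flower development, lay below in OX ZFHD10, with 38 of 98 (38.8%, against 62.3%, 53.1 to 71.4%), and inside the central 95% in OX TZP, with 35 of 98 (35.7%, against 39.1%). The 31 lists and families gave 62 comparisons, of which 23 lay outside the central 95% by percentile, where 3.10 would by chance if genes had islands independently. Neighbouring members can share an island, as XTH18 and XTH24 did in OX ZFHD10, so chance may give more than 3.10. On the limit of the central 95% lay 4 of the 23, namely the cell wall list in OX ZFHD10 and the clock and housekeeping lists and GRAS factors in OX TZP. Over gene bodies the MYB and WRKY shares in OX TZP and the Aux/IAA and F-box shares in OX ZFHD10 were inside it, histone genes lay above it in OX TZP, and cytochrome P450 genes lay below it in both lines. Without the pseudogene-rich bins, ethylene-responsive factors in OX TZP and GRAS factors in OX ZFHD10 lay on its upper limit.

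Where islands lay relative to genes differed between the lists, although this difference was not tested. OX ZFHD10 islands were centred at gene ends in 74.2% of cases (73.5 to 74.8), against 40.2% by placement, and OX TZP islands in 47.0% (46.1 to 47.9), against 40.2%. Midpoints inside protein-coding genes made up 65.0% of OX TZP islands (64.1 to 65.8), against 54.1% by placement, and 41.5% of OX ZFHD10 islands (40.7 to 42.2), against 54.2%. Gene interiors, beyond the gene ends, held 40.2% of OX TZP and 13.8% of OX ZFHD10 midpoints. Annotated pseudogenes held 2.41% and 0.298%, against 8.74% and 8.72% by placement. Placement within 100 kb bins left the gene-end ratio of OX TZP at 1.05 and that of OX ZFHD10 at 1.59. It gave 61.4% and 64.0% inside protein-coding genes and 4.24% and 2.72% in pseudogenes, so that the OX TZP excess inside genes and the lack of pseudogenes in OX TZP and OX ZFHD10 were smaller against it.

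**Figure D4:**
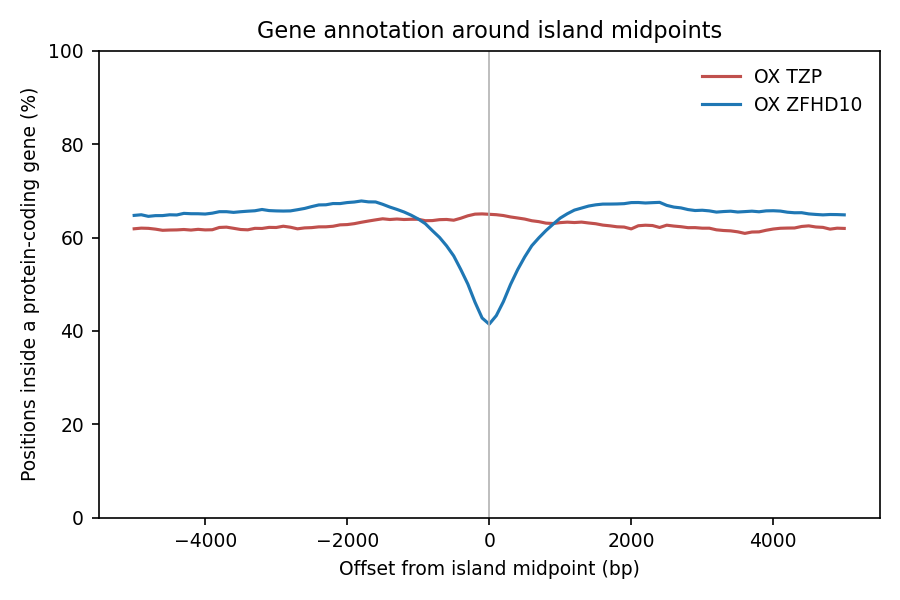
Share of positions inside a protein-coding gene (vertical axis, %) at each offset from the midpoints of the OX TZP and OX ZFHD10 islands (horizontal axis, bp). The OX ZFHD10 line dips to 41.5% at the midpoint, and the OX TZP line stands at 65.0% there.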

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

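All tests in this part were chosen after the results were seen.

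Signal appeared outside the nuclear chromosomes, where the OX TZP list had 9 islands with 83710 reads, or 3.96% of its island reads, and the OX ZFHD10 list had none. The chloroplast island, at positions 110251 to 128400, held 34118 reads, and the other 8 islands lay on the mitochondrial genome.

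The share of midpoints inside protein-coding genes, over that of placement, was 1.20 in OX TZP and 0.765 in OX ZFHD10, so that the whole lists lay on opposite sides of placement. With placement within 100 kb bins the ratios were 1.06 and 0.648, and 1.05 and 0.642 when the pseudogene-rich bins were also left out, so most of the OX TZP excess went with the bins in which its islands lay. This difference between the lines was not tested. In OX TZP the share inside genes was 74.1% (72.3 to 75.8) in the least dense of 5 equal groups of islands and 50.6% (48.6 to 52.6) in the densest, below the 54.1% of placement of the whole list, and 53.9% there without the pseudogene-rich bins. In OX ZFHD10 it also fell, from 47.4% (45.7 to 49.1) to 34.8% (33.2 to 36.5).

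The island over TZP in OX TZP ranked 3 of its list. Extra copies of the TZP sequence in the overexpression line are a candidate explanation, and 100% of the island lay inside the annotated gene, where such copies would place it. Of 2 OX ZFHD10 islands at TZP, from a line with no TZP copy named in its label, the longer also lay wholly inside the gene and the other to 22.5%, so that binding at TZP and extra copies cannot be told apart from the bounds, in the absence of exons and strand. Carry-over of OX TZP reads into the OX ZFHD10 library would also give an island at TZP there, at a rate of 0.382 by read density. At that rate 7 other nuclear OX TZP islands would reach 192 reads per kb, the 5th percentile of OX ZFHD10 islands, and 0 of them overlapped an OX ZFHD10 island. Of these 7, 1 lay outside the pseudogene-rich bins, and the control library that shaped the calls in such bins is unknown. Some OX TZP organelle islands would reach that density too, such as the chloroplast island with 1880 reads per kb. The OX ZFHD10 list had no organelle island, which carry-over alone would not give. Calls on organelle genomes also depend on the unknown control, and each line had 1 library. Carry-over and binding at TZP therefore cannot be told apart from these islands. Binding of both proteins at TZP was not tested.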

How the results depend on the processing

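Alternatives without the pseudogene-rich bins, placement matched on annotation class and the shares inside genes were added after the data were seen; the others were planned. The overlap of the lists stayed above placement in every alternative run, with ratios of 1.65 to 2.84 for OX TZP and 1.58 to 2.82 for OX ZFHD10, against 2.02 and 1.88. The share of islands itself fell when a larger overlap was asked for. With at least 50% of the island overlapped it was 33.2% in OX TZP and 21.6% in OX ZFHD10. With reciprocal overlap of at least 50% it was 19.9% and 14.4%. The gene-end ratio stayed above placement in both lines. The ratio of shared to unshared islands in median reads moved from 1.03 to 1.1 in OX TZP and from 1.07 to 1.49 in OX ZFHD10 when taken per island and not per kb; shared islands are longer, with a median of 950 against 900 bp and 1000 against 750 bp. With the islands of most reads, 6833 genes had an OX TZP island, 10819 an OX ZFHD10 island and 3755 both, since fewer islands entered. Of the gene lists, 11 shares left the central 95% by percentile, 3 of them on its limit (cell wall expansion in OX ZFHD10, clock and housekeeping in OX TZP), and 4 did over gene bodies with random lists matched on gene length; the cause was not tested. Those 4 were light signalling and housekeeping in OX ZFHD10 and stress response in both lines. No alternative run reversed a difference that lay outside the central 95%, while some gene list and family differences inside it changed sign. Motifs and their 3 alternatives were not run, for want of sequence. No paired analysis was possible because each group had 1 library, and no library could be left out. Whole-library depth is unknown, so the smaller OX TZP list may hold fewer genes because of depth, which the 6833 and 10819 genes above do not settle.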

Other observations

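Of the tests below, placement matched on annotation class was fixed before its result was seen, and the others were chosen afterwards.

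Small RNA genes differed in how often an island covered them. Transfer RNA genes had an OX ZFHD10 island in 272 of 625 cases (43.5%, 39.7 to 47.4), against 15.2% by placement within 100 kb bins, and an OX TZP island in 110 (17.6%, 14.8 to 20.8), against 11.2%. Spliceosomal small nuclear RNA genes had an OX ZFHD10 island in 39 of 82 cases (47.6%, 37.1 to 58.2), against 17.6%, and small nucleolar RNA genes in 88 of 287 (30.7%, 25.6 to 36.2), against 17.6%. The OX TZP shares of both kinds were inside the central 95% of placements, with 14 of 82 and 32 of 287. MicroRNA genes were inside it in both lines, with 12.0% in OX TZP and 12.3% in OX ZFHD10.

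Of the 20 densest OX TZP islands, 11 lay in pseudogene-rich bins, where 4.39% of the whole list lay, and 2 overlapped an OX ZFHD10 island. Of the 20 densest OX ZFHD10 islands, 0 lay in such bins and 10 overlapped an OX TZP island. The longest OX TZP island, of 31.9 kb at chromosome 3 positions 13040651 to 13072600, held 12247 reads in such a bin.

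Every housekeeping gene examined had an OX ZFHD10 island at a gene end, and a candidate explanation is that immunoprecipitation recovered active or accessible chromatin whatever the gene. Families broadly active in seedlings should then all lie above their random lists in OX ZFHD10, but ribosomal protein genes lay at percentile 99.1 (82.1% of 67 genes), histone genes at 48.4 (69.6% of 23) and chlorophyll a/b binding genes at 10.1 (52.4% of 21), so the test left the explanation open. The overlap of the lists is not accounted for by the annotation classes used here alone, since it was 1.65 times that of placement on positions of the same class. These classes do not tell the start of a gene from its other end, so a common preference for either stays open. Binding of ZFHD10 at many active genes was not tested and stays open too.

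A pair of OX TZP islands, picked because they are long, covered 98.9% of a 35.4 kb stretch of chromosome 2, from 15484701 to 15520050, with 7 genes that include RAX2, MEMB11 and the auxin transporter gene ABCB1. Stretches of equal length to either side were covered to 25.2% and 11.7%, and OX ZFHD10 islands covered 28.9% of it. A copy gain of the segment in the overexpression line is a candidate explanation, which needs an even density across it. The pair had 239 and 233 reads per kb, a ratio of 1.03 (0.982 to 1.07). As 13.8% of 11157 neighbouring island pairs lay as close, copy gain and broad enrichment cannot be told apart from this.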
